A study of Mus musculus with 32 samples.

How the data were processed

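Expression was measured on 32 single-channel bead arrays (Illumina MouseRef-8), 16 of hippocampus and 16 of gastrocnemius muscle from 23-month-old female C57BL/6J mice. Each tissue has 4 groups of 4 arrays: saline, and AICAR at 500 mg/kg/day for 3, 7 or 14 days. Total RNA was extracted with a column kit, and amplified, biotin-labelled RNA was stained with streptavidin-Cy3, per the labels. The submitters' processing notes name BeadStudio 1.6.0. The first deposited file holds the raw signal of each probe on each array, an intensity on a linear scale that the authors neither normalized nor corrected for background. Beside each intensity the deposited file gives a detection p-value, which compares the probe with the negative controls of its array. The deposited series values are a score: checked on the files, each is the log2 intensity minus its array's mean, divided by its array's SD. No genome build is stated and none is needed for probe values, so probe positions are not given here. Probe names come from the platform table: 23978 of 25697 probes carry 1 gene symbol, 1719 carry none, and 16593 symbols are covered. Of the named probes, 23962 matched a RefSeq gene table by Entrez ID, and 0 symbols changed.

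The values used here were computed from the intensities with limma 3.58.1 in R 4.3.3: normexp background correction from the detection p-values (neqc, offset 16), then quantile normalization within each tissue, then log2. Probes detected at p below 0.05 on at least 4 of the 16 arrays of a tissue were tested, which left 13659 probes for 9534 genes in hippocampus and 12977 probes for 9030 genes in muscle. A linear model with 1 mean per group (lmFit, contrasts.fit, eBayes) gave each comparison: every AICAR group against saline, and the AICAR groups against each other. A joint fit of all 32 arrays over the 11315 probes kept in both tissues tested whether the change from saline differed between muscle and hippocampus. It had no term for the animal and treated the arrays of both tissues as independent. The p-values are two-sided, adjusted over the probes of each comparison by Benjamini and Hochberg, and called below 0.05. Errors beside a log2 fold change are the model's standard errors (SE). Errors beside a group mean are SDs over 4 arrays. Depth has no counterpart in counts on arrays, and the number of arrays limits the precision.

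Gene lists for AMPK and exercise biology, for both tissues and for the cell types that a dissection could hold were written before the data were examined. Each list was tested with camera (limma, preset correlation 0.01) on the brightest probe of each gene, with adjustment over the 38 lists of hippocampus or the 33 of muscle. Beside each called list stands camera's adjusted p with a correlation estimated from the list itself. A count "adjusted over the list alone" applies the correction to the list's members only.

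The genes named below follow a rule also fixed before the data were examined. For each comparison with saline it takes the 8 symbols with the largest rise and the 8 with the largest fall among called probes whose 4 AICAR arrays all lie on 1 side of the saline mean. Where fewer than 5 passed in a direction, it takes the 5 with the smallest p, reported as not past the threshold. From each list that was called or held at least 3 called members it takes up to 4 members with the smallest p. A fixed panel of 8 genes per tissue is added: Prkaa1, Prkaa2 and Ppargc1a in both, Bdnf, Ntrk2, Dcx, Neurod1 and Vegfa in hippocampus, and Ppard, Slc2a4, Cpt1b, Pdk4 and Ucp3 in muscle. For comparisons between durations and between tissues it takes the 5 largest changes in each direction. The text gives these genes in part where there are many. The probe with the highest mean signal stands for a gene with several probes. For a gene undetected in all arrays of 1 group, a lower bound of the fold is computed against the detection limit and written as "at least".

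The procedure was tested on simulated data with known changes in 14-day groups. It recovered 67% of 1.5-fold and 96% of 2-fold changes in hippocampus with 7 calls among unchanged probes, and 74% and 94% in muscle with 9. For the tissue difference it recovered 46% and 88% with 11 such calls. In a comparison simulated as unchanged it made 0 calls, and a list shifted by 0.2 was called in both tissues with 0 other lists. Each probe was simulated independently of the others, so the simulation does not test calls where genes move together or sets of arrays differ. When the real hippocampal arrays of the 14-day comparison were regrouped, a median of 3 lists and up to 11 were called.

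Most alternatives changed 1 choice, while the authors' series values change the background step, the normalization and the scale together, and the unadjusted p comes with a fold limit. The alternatives were no background correction, median scaling in place of quantile normalization, the authors' series values, no filter on dim probes, probes detected on all 16 arrays, a replicate block, a fit of the compared groups alone, array weights, a trended and robust variance, an unadjusted p with at least 1.5-fold change, and each array left out in turn. All samples and both deposited files were used. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.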

Results

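AICAR is a cell-permeable nucleoside whose phosphorylated form activates AMP-activated protein kinase (AMPK). By the series title, the study asked how the compound bears on mental performance and coordinated movement at different ages, and the arrays profile aged mice. Female C57BL/6J mice of 23 months received AICAR at 500 mg/kg/day for 3, 7 or 14 days, or saline for 3 days. Hippocampus and gastrocnemius muscle were taken 33 days after the last injection, following perfusion with saline. Each of the 8 groups holds 4 arrays. Since saline was injected for 3 days only, the number of injections cannot be separated from AICAR at 7 and 14 days. Nothing states whether both tissues came from the same mice or whether each replicate is a separate mouse. The errors and p-values below rest on taking the arrays as independent. Between 11695 and 13225 probes were detected per array.

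The arrays of each tissue fell into 2 sets, saline with 3 days and 7 with 14 days. The first principal component carried 36.0% of the variance in hippocampus and 44.9% in muscle and separated these sets. The background signal followed the same split. In hippocampus it was 122.4 ± 3.2 (SD, n = 4) in saline, 117.6 ± 2.6 at 3 days, 158.8 ± 4.3 at 7 days and 150 ± 3.2 at 14 days. In muscle it was 129 ± 5.3, 119.1 ± 3.7, 164.1 ± 4.7 and 147.4 ± 5.5. The sample numbers in the labels run in 4 blocks of 8, and each block holds both tissues of 1 treatment, so handling in blocks cannot be told apart from treatment.

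**Figure D1:**
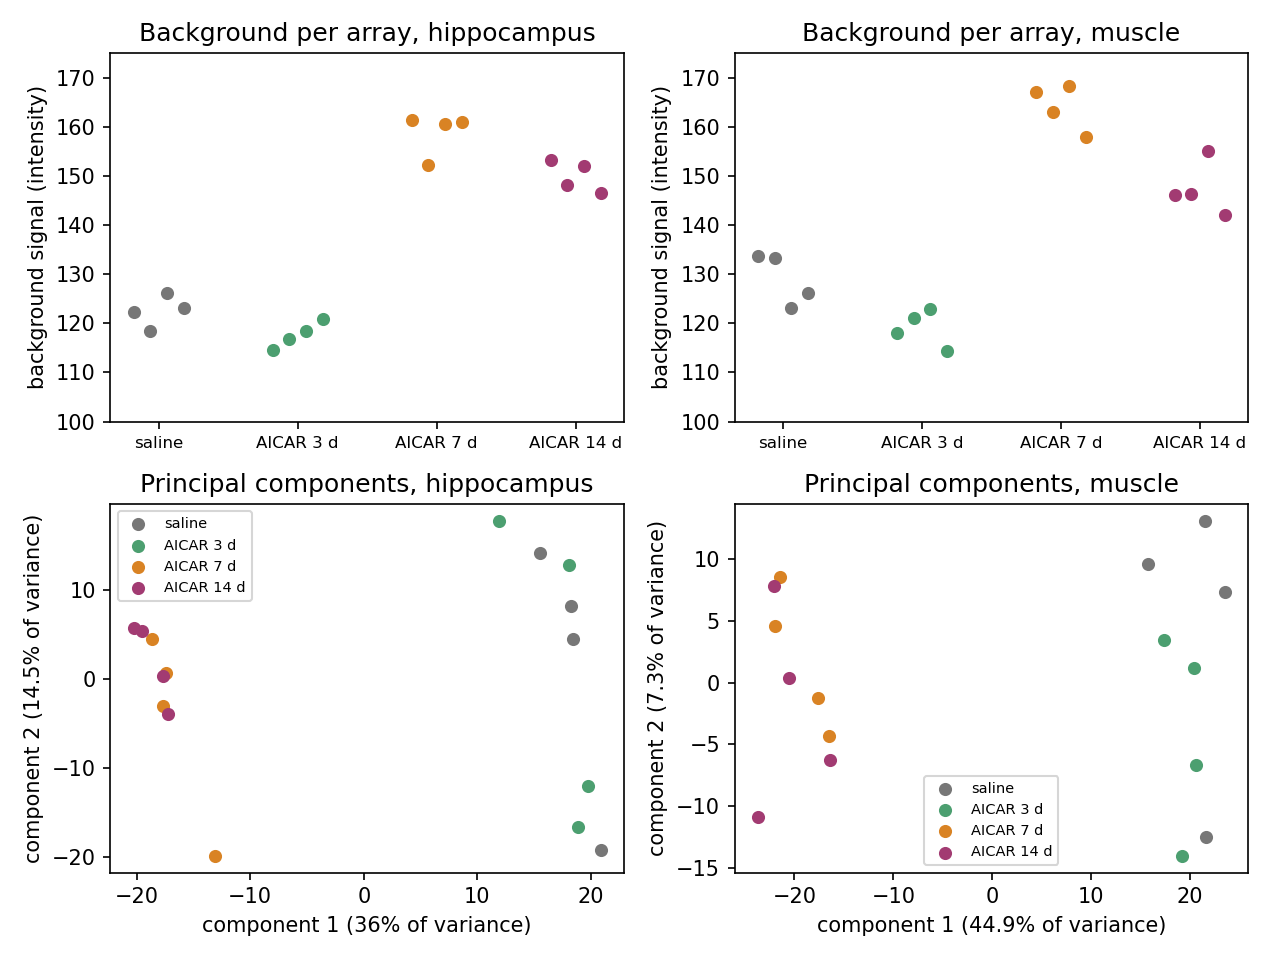
Background signal of each array by group (top, intensity units) and the first 2 principal components of each tissue's arrays (bottom), with 1 point per array. Saline and 3-day arrays lie at or below a background of 133.6, and 7- and 14-day arrays at or above 142.1.

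In the aged hippocampus no probe passed the threshold a month after 3 days of AICAR. Numbl, a Notch regulator of neural progenitors, was 0.52 ± 0.10 higher on the log2 scale than in saline (SE, n = 4, adjusted p = 0.273). The leukocyte tetraspanin Cd53 stood at 0.73 ± 0.15 and the caveolar protein Cav1 at 0.44 ± 0.10. Among lower probes, the nucleolar Taf1d stood at -0.71 ± 0.12 (adjusted p = 0.250, the smallest of the comparison), the nuclear pore protein Nup50 at -0.86 ± 0.17 and Tmem132d at -0.45 ± 0.09. Other probes of Taf1d (0.07) and Nup50 (-0.56 and 0.15) did not pass either.

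After 3 days 4 lists were called upward at the preset correlation, 3 of them of immune genes, with no single member past the threshold over all probes and no call left with an estimated correlation. Of 14 microglia markers, 13 had a positive change with a median of 0.17 (camera adjusted p = 0.0012, 0.494 with an estimated correlation), led by Fcrls (0.26 ± 0.07), Trem2 (0.21 ± 0.11) and Ly86 (0.21 ± 0.11). Adjusted over the list alone, 1 of the 14 was higher. Of 17 interferon-response and MHC class I genes, 15 were positive with a median of 0.18 (adjusted p = 0.0054, 0.565 with an estimated correlation), among them Gbp3 (0.43 ± 0.16), Ifit3 (0.39 ± 0.19) and B2m (0.25 ± 0.14), and 0 passed adjusted over the list alone. Of 20 complement and glial ageing genes, 14 were positive with a median of 0.15 (adjusted p = 0.0306, 0.565 with an estimated correlation, 0 adjusted over the list alone), among them C1qa (0.31 ± 0.17) and the beta-glucan receptor Clec7a, undetected in saline and at least 1.19-fold higher. The 4 red blood cell markers had a median of 0.47 (adjusted p = 0.04999, 0.494 with an estimated correlation, 0 adjusted over the list alone), with Hbb-bt at 0.54 ± 0.37 and the haem enzyme Fech at 0.30 ± 0.12. In place of 4 called lists there were 0 without 3-day replicate 4 and 0 with no filter. There were 2 without saline replicate 1, with array weights or for probes detected on all 16 arrays, and 10 in the authors' series values. In the fixed panel Vegfa stood at 0.31 ± 0.12, Ppargc1a at -0.16 ± 0.10, Ntrk2 at -0.07 ± 0.10, Dcx at -0.04 ± 0.20 and Prkaa2 and Bdnf at 0.00, and none of these 6 passed. Prkaa1 has no probe under that symbol, and the Neurod1 probe was not detected.

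By limma, 0 of 13659 hippocampal probes passed after 3 days, and 823 passed at an unadjusted p below 0.05, where 683 would by chance.

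After 7 days the hippocampus differed from saline at 3696 probes, 1787 higher and 1909 lower. Ptgds, the prostaglandin D synthase abundant in brain fluids and meninges, was 2.85-fold higher (1.51 ± 0.44 log2, n = 4, adjusted p = 0.0191). The actin-binding calponin Cnn3 rose 2.79-fold (1.48 ± 0.12, adjusted p = 8.7e-06). The clock repressor Nr1d2 rose 2.66-fold (1.41 ± 0.18), the proteasome lid subunit Psmd11 2.59-fold (1.37 ± 0.13) and Calml4, a calmodulin-like gene of choroid plexus, 2.56-fold (1.36 ± 0.43, adjusted p = 0.0279). Antxr1, undetected in saline, was at least 2.14-fold higher, and Atxn2l, also undetected in saline, at least 1.75-fold. The other probe of Antxr1 was not past as a rise. The immediate early transcription factors Fos (-1.17 ± 0.33, adjusted p = 0.0173) and Egr2 (-0.98 ± 0.26) fell. So did the PIWI protein gene Piwil1 (-1.12 ± 0.13), the amino acid transporter Slc6a19 (-1.09 ± 0.12) and Pxt1 (-0.98 ± 0.10). Zpld2, undetected at 7 days, was at least 1.69-fold lower.

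Genes for ribosomal proteins and for defence against oxidants were the called groups at 7 days. Of all 9534 genes tested, 1154 rose and 1469 fell on their brightest probe. Of 37 ribosomal protein genes 13 rose, 2 fell and 22 did not pass (13 and 2 adjusted over the list alone), with Rps21 at 0.91 ± 0.07, Rpl5 at 0.87 ± 0.10 and Rps10 at 0.60 ± 0.09. The list's adjusted p was 0.0194, and 0.747 with an estimated correlation. Its median was 0.09 on the log2 scale, and -0.05 in the authors' series values, which are in units of array SD. Of 22 antioxidant genes 7 rose and 0 fell (8 and 1 adjusted over the list alone, median 0.16). Risers included the peroxidase Prdx1 (0.74 ± 0.09), the glutathione peroxidase Gpx4 (0.52 ± 0.08), mitochondrial Sod2 (0.51 ± 0.09) and Gstm1 (0.42 ± 0.06, other probe not past as a rise). The antioxidant list's adjusted p was 0.0194, and 0.410 with an estimated correlation. No list remained called without 7-day replicate 1 or saline replicate 1 or 2, and 4 were called without saline replicate 3. Median scaling and the authors' series values each gave 0 called lists. In the panel, Prkaa2, the catalytic alpha-2 subunit of AMPK, fell by 0.50 ± 0.10 (adjusted p = 0.0026), and the neurotrophin Bdnf fell by 0.30 ± 0.08 (adjusted p = 0.0106). Under median scaling, which moved the median of all probes from -0.03 to 0.18, these were -0.21 and -0.02 and no longer passed, and their second probes (-0.13 and -0.05) did not pass. Vegfa stood 0.40 ± 0.12 higher (adjusted p = 0.0254), with its other probe at -0.12. Ppargc1a (-0.18 ± 0.10), Ntrk2 (0.16 ± 0.10) and Dcx (0.25 ± 0.20) did not pass, while another probe of Ntrk2 (0.57) and of Dcx (0.64) did.

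Of the 27 called probes named at 7 days, 25 had AICAR and saline arrays that did not overlap. Most named probes were picked from these same values by large change or small p. Little overlap is therefore largely a result of the choice, here and in the like counts below. Ptgds lost its call without saline replicate 4 (1.26, adjusted p = 0.0625), and Fos without 7-day replicate 2 (-0.96, adjusted p = 0.0588). Calml4 lost it without any 1 array except 7-day replicate 4 and saline replicate 3 (1.11 to 1.34, adjusted p = 0.0569 to 0.0885), and Vegfa without 7-day replicate 3 or 4 or saline replicate 1 or 3 (0.32 to 0.38, adjusted p = 0.0598 to 0.0807). The share of called probes that were higher was 48.3%, and 93.2% of 3527 under median scaling, so the balance of rises and falls depends on the scaling. Different probes of a gene seldom moved together: across 2432 genes the changes of the 2 brightest probes had r = 0.14 (genes are not independent replicates). Where both passed, 64.6% of the pairs went the same way (133 pairs, 95% CI 57.6 to 71.1%).

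After 14 days the hippocampus differed from saline at 4033 probes, 1865 higher and 2168 lower. Calml4 was 3.51-fold higher (1.81 ± 0.43, n = 4, adjusted p = 0.0054) and Ptgds 2.94-fold (1.55 ± 0.44, adjusted p = 0.0154). Cnn3 rose 2.91-fold (1.54 ± 0.12), Psmd11 2.54-fold (1.34 ± 0.13), the endothelial proteoglycan Esm1 2.44-fold (1.28 ± 0.41), Tmbim1 2.44-fold (1.28 ± 0.16) and the kelch protein gene Klhdc3 2.40-fold (1.26 ± 0.10). The thyroid hormone-inactivating deiodinase Dio3 was 2.42-fold lower (-1.27 ± 0.19, adjusted p = 2.2e-04) and the neuronal gene Bex1 2.22-fold lower (-1.15 ± 0.14). Slc6a19 (-1.08 ± 0.12), Fos (-1.04 ± 0.33) and Zpld2 (-1.05 ± 0.14) also fell, and Tssk2, undetected at 14 days, was at least 1.32-fold lower. The chemokine Ccl25 was 1.24 ± 0.16 higher at its brightest probe while its other probe was -0.54 and passed. Pacsin3 was -1.12 ± 0.15 while another of its probes was 0.83 and passed.

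The called lists at 14 days held ribosomal, mitochondrial, antioxidant and immune genes. Of all 9534 genes tested, 1200 rose and 1665 fell on their brightest probe. Of 37 ribosomal protein genes 15 rose, 3 fell and 19 did not pass (16 and 4 adjusted over the list alone, adjusted p = 0.0011, 0.519 with an estimated correlation), with Rps21 at 0.96 ± 0.07, Rpl5 at 0.92 ± 0.10 and Rps10 at 0.72 ± 0.09. Its median was 0.10 on the log2 scale, and 0.00 in the authors' series values (units of array SD). Of 32 complex I genes 10 rose and 3 fell (the same adjusted over the list alone, adjusted p = 0.0095, 0.519 with an estimated correlation), including Ndufb10 (1.11 ± 0.15) and Ndufb3 (0.78 ± 0.10), and Ndufb11, undetected in saline, was at least 1.30-fold higher. Of 38 genes of complexes II to V 9 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0341, 0.519 with an estimated correlation), including Uqcrb (0.96 ± 0.11), Sdhc (0.58 ± 0.11) and Cox4i1 (0.47 ± 0.06). Of 22 antioxidant genes 8 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 0.0049, 0.444 with an estimated correlation), with Prdx1 at 0.82 ± 0.09, Gpx4 at 0.63 ± 0.08 and Sod2 at 0.60 ± 0.09.

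Of 17 interferon-response and MHC class I genes 7 rose and 0 fell at 14 days, also adjusted over the list alone, with a median of 0.39 (adjusted p = 0.0049, 0.519 with an estimated correlation). The immunoproteasome subunits Psmb9 (0.68 ± 0.15) and Psmb8 (0.60 ± 0.16), Ifi27 (0.60 ± 0.16) and the MHC class I light chain B2m (0.52 ± 0.14) were among them, and the second probes of Ifi27 (0.54) and B2m (0.48) passed too. Of 20 complement and glial ageing genes 5 rose and 1 fell, also adjusted over the list alone, with a median of 0.36 (adjusted p = 0.0433, 0.550 with an estimated correlation). These included the microglial adaptor Tyrobp (1.09 ± 0.18), C1qa (0.77 ± 0.17) and the astrocyte filament Gfap (0.68 ± 0.16), while Cst7 was -0.59 ± 0.13. Of 14 microglia markers 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.484), with P2ry12, a marker of resting microglia, at -0.57 ± 0.11 and Aif1 at 0.50 ± 0.11 on its brightest probe and -0.44, also past, on the other. The 14 choroid plexus markers had a median of 0.92 (adjusted p = 0.168), with 1 higher and 1 lower past the threshold, also adjusted over the list alone. Median scaling and the authors' series values each gave 2 called lists in place of 6.

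Single genes of neurogenesis and the clock moved in both directions at 14 days, as did genes at large (1200 of 9534 rose and 1665 fell on their brightest probe). The proneural factor Neurod2 rose by 0.95 ± 0.09 and the stem cell factor Sox2 was -0.67 ± 0.08. Of 19 neurogenesis genes 2 rose and 3 fell, also adjusted over the list alone (list adjusted p = 0.836), which is close to the shares over all genes. Among 17 clock genes 4 rose and 2 fell (5 and 2 adjusted over the list alone, list adjusted p = 0.471). Nr1d2 was 1.03 ± 0.18, Tef 0.73 ± 0.12, Per1 0.61 ± 0.11 and Ciart -0.53 ± 0.08 (second probe -0.54 and past), whereas the other probes of Per1 (-0.34) and Tef (-0.36) were negative and did not pass. Prkaa2 was -0.49 ± 0.10 (adjusted p = 0.0026), Ppargc1a, the coactivator of mitochondrial biogenesis, -0.35 ± 0.10 (adjusted p = 0.0120) and Vegfa 0.40 ± 0.12 (adjusted p = 0.0230). The second probe of Prkaa2 was not past as a fall. Under median scaling, which put the median of all probes at 0.07, Prkaa2 (-0.32), Ppargc1a (-0.18), Ciart (-0.35) and P2ry12 (-0.42) did not pass. Nor did Ppargc1a pass in the authors' series values (-0.15, in units of array SD and not log2). Bdnf (-0.12 ± 0.08), Ntrk2 (0.20 ± 0.10) and Dcx (-0.08 ± 0.20) did not pass.

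In 48 of the 51 called probes named at 14 days the AICAR and saline arrays did not overlap. Ptgds lost its call without saline replicate 4 (1.30, adjusted p = 0.0514). Esm1 lost it without saline replicate 1 or 2 or 14-day replicate 1, 2 or 3 (1.03 to 1.30, adjusted p = 0.05001 to 0.0850). Fos lost it without saline replicate 2, 3 or 4 or 14-day replicate 1 or 2 (-1.06 to -0.90, adjusted p = 0.0516 to 0.0853) and with a trended, robust variance (adjusted p = 0.0502). Vegfa lost it without 14-day replicate 2 or saline replicate 1 or 3 (0.32 to 0.35, adjusted p = 0.0665 to 0.0766), and its other probe was -0.23. Of the called probes 46.2% were higher, and under median scaling 87.5% of 2179 were. Across 2432 genes the 14-day changes of the 2 brightest probes had r = 0.18, and where both passed 160 of 251 pairs (63.7%) went the same way. Of 43 probes at least 2-fold higher whose gene had another tested probe, 14 had another that passed upward, 3 another that passed downward and 26 neither.

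**Figure D2:**
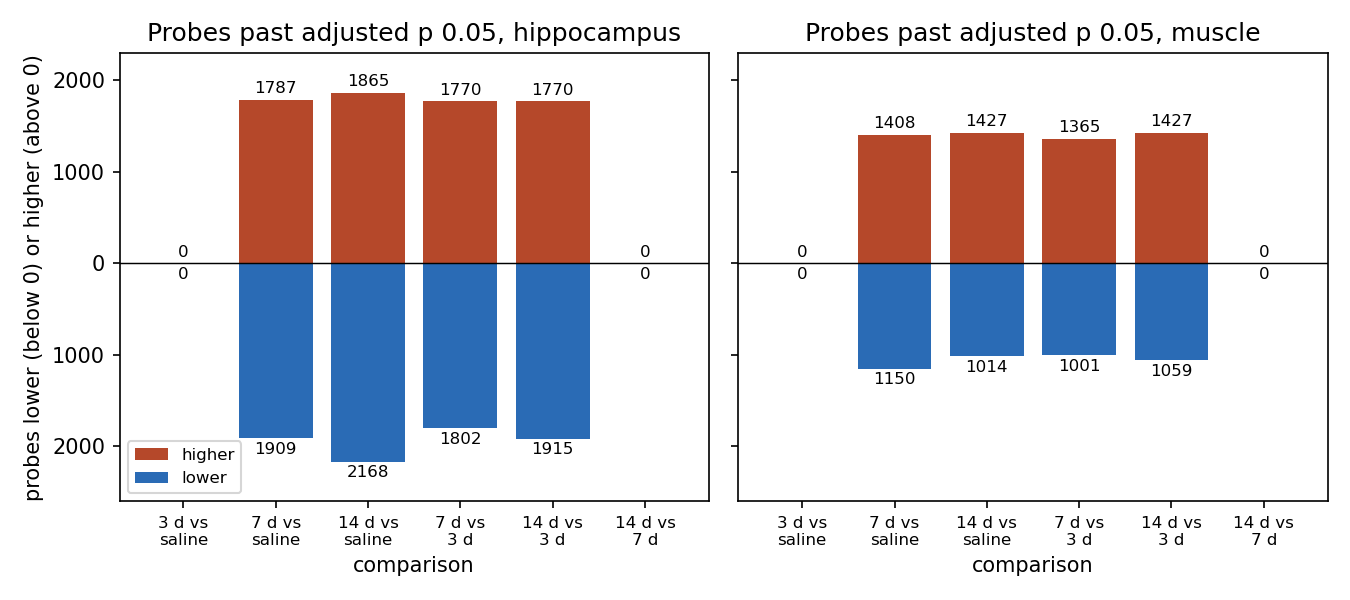
Probes past an adjusted p of 0.05 in each comparison, higher above 0 and lower below 0, for hippocampus (left) and muscle (right). No probe passed for 3 days against saline or 14 against 7 days in either tissue, while the comparisons across the 2 sets of arrays gave 2366 to 4033.

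In hippocampus the 7- and 14-day groups resembled each other and both differed from 3 days. Against 3 days, Cnn3 was 1.36 ± 0.12 higher at 7 days and 1.42 ± 0.12 at 14 days (n = 4 per group). At 14 days Calml4 (1.58 ± 0.43, adjusted p = 0.0132), Klhdc3 (1.37 ± 0.10), AI837181 (1.34 ± 0.16) and Ptgds (1.27 ± 0.44, adjusted p = 0.0430) were the other largest rises. The largest falls were in Fos (-1.17 ± 0.33, adjusted p = 0.0177), Zpld2 (-1.08 ± 0.14), Dio3 (-1.05 ± 0.19), Bex1 (-1.05 ± 0.14) and the splicing factor Rbfox2 (-0.93 ± 0.11). Fos was -1.29 ± 0.33 at 7 days. In all, 3572 probes differed between 7 and 3 days (1770 higher, 1802 lower) and 3685 between 14 and 3 days (1770 higher, 1915 lower). Under median scaling these were 4991 with 95.6% higher and 2964 with 94.2% higher, in place of 49.6% and 48%. By limma 0 probes differed between 14 and 7 days, and 404 did at an unadjusted p below 0.05. Of the probes called against saline, 1517 rose and 1527 fell at both durations, which share their saline arrays, and 0 moved in opposite directions. The 7- and 14-day changes had r = 0.91 across probes, and 0.70 with the saline arrays split so that none was shared. Simulations of unchanged groups that share the saline arrays gave a mean r of 0.50, with a range of -0.11 to 0.87. Ptgds at 14 against 3 days lost its call without 14-day replicate 1, 3 or 4 or 3-day replicate 2 or 4 (0.76 to 1.37, adjusted p = 0.0538 to 0.118), and also with no filter (adjusted p = 0.0687), in a fit of the compared groups alone (0.106), with array weights (0.0676) and with a trended, robust variance (0.0725). Fos lost it without 14-day replicate 2 or 3-day replicate 3 or 4 (-1.02 to -0.94, adjusted p = 0.0518 to 0.0567).

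**Figure D3:**
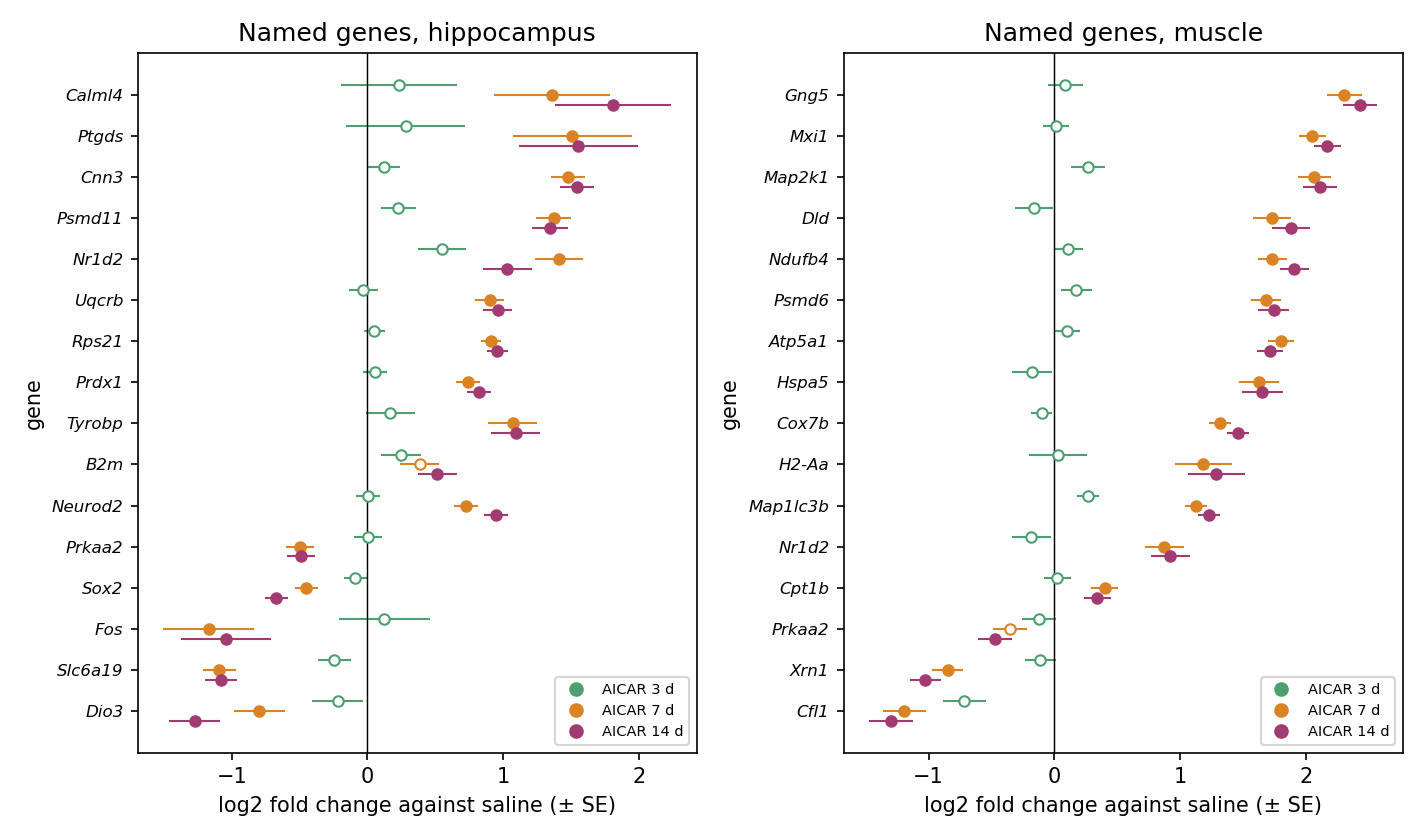
Log2 fold change against saline ± SE for 16 named genes per tissue after 3, 7 and 14 days (n = 4 per group), with filled points past an adjusted p of 0.05. Nearly coincident 7- and 14-day values contrast with 3-day values nearer to 0, as for Cnn3 in hippocampus and Gng5 in muscle. Most of these genes were named for their change at 7 or 14 days, so the contrast is largely a result of the choice. All durations share the saline arrays.

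In muscle, 3 days of AICAR left no probe past the threshold a month later. The ubiquitin ligase gene Trim23 stood at -0.60 ± 0.10 (n = 4, adjusted p = 0.108), the zinc finger genes Zfp644 at -0.47 ± 0.08 and Zfp24 at -0.73 ± 0.14 and the vesicle SNARE Vamp7 at -0.58 ± 0.11. The other 2 probes of Trim23 (-0.52 and -0.49) lay on the same side. Among higher probes were the microtubule-end binder Mapre3 (0.39 ± 0.08), the apoptosis repressor Nol3 (0.48 ± 0.11), Ifngr2 (0.39 ± 0.09) and Grcc10 (0.30 ± 0.07). The panel genes of fuel use lay close to saline or varied widely: Slc2a4 at 0.03 ± 0.07, Cpt1b at 0.02 ± 0.11, Ppargc1a at -0.01 ± 0.09, Prkaa2 at -0.12 ± 0.13, Pdk4 at -0.74 ± 0.36 and Ucp3 at -0.72 ± 0.37, none past the threshold. Prkaa1 has no probe under that symbol, and the Ppard probe was not detected. By limma 0 of 12977 probes passed, and 1434 did at an unadjusted p below 0.05, where 649 would by chance. This 0 became 1 to 39 under some settings: 13 without background correction, 4 with median scaling, 39 in the authors' series values, 5 for probes detected on all 16 arrays, 10 with a trended, robust variance and 1 without 3-day replicate 3, where Trim23 passed (-0.69, adjusted p = 0.0435). No list was called. Median scaling gave 1, the authors' series values 7, and leaving out 3-day replicate 2 gave 1.

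After 7 days muscle differed from saline at 2558 probes, 1408 higher and 1150 lower. The G protein subunit Gng5 rose 4.95-fold (2.31 ± 0.14, n = 4, adjusted p = 7.3e-09), the MYC antagonist Mxi1 4.15-fold (2.05 ± 0.10), the kinase Map2k1 4.2-fold (2.07 ± 0.13) and prothymosin Ptma 3.88-fold (1.95 ± 0.11). Beta-globin Hbb-bt was 4.8-fold higher (2.26 ± 0.59, adjusted p = 0.0122). The actin-severing cofilin gene Cfl1 was 2.29-fold lower (-1.19 ± 0.17, adjusted p = 8.1e-05), the noradrenaline transporter Slc6a2 1.95-fold lower (-0.96 ± 0.18) and Mtmr3 -0.91 ± 0.14. The complement gene C1qa, undetected at 7 days, was at least 1.77-fold lower, and Dipk2b at least 1.21-fold.

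Energy and protein-quality genes held large single rises at 7 days, though no list was called. Of all 9030 genes tested, 929 rose and 772 fell on their brightest probe. Of 38 genes of complexes II to V 8 rose and 0 fell, also adjusted over the list alone, with a median of -0.01, a mean of 0.22 and an adjusted p of 0.0729. The risers included the ATP synthase subunits Atp5a1 (1.80 ± 0.10) and Atp5e (1.61 ± 0.13), Sdhd (1.59 ± 0.12) and Cox7b (1.32 ± 0.08). Of 28 proteasome genes 7 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.178), with Psmd6 at 1.68 ± 0.12, its second probe at 1.79 and past, and Psmc6 at 1.5 ± 0.19. Of 20 heat shock and unfolded protein genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0892), with the mitochondrial chaperonin Hspe1 at 1.17 ± 0.09 and the endoplasmic reticulum chaperone Hspa5, undetected in saline, at least 2.82-fold higher. Of 12 macrophage and leukocyte markers 3 rose and 4 fell (3 and 5 adjusted over the list alone, adjusted p = 0.723). The 5 red blood cell markers had a median of 0.81, 1 past the threshold and 2 adjusted over the list alone (adjusted p = 0.187). The carnitine palmitoyltransferase Cpt1b, which admits fatty acids to mitochondria, rose by 0.40 ± 0.11 (adjusted p = 0.0139), though its other probe was -0.05. Prkaa2 (-0.35 ± 0.13, adjusted p = 0.0794), Ppargc1a (-0.20 ± 0.09), Slc2a4 (0.15 ± 0.07), Pdk4 (0.30 ± 0.36) and Ucp3 (0.24 ± 0.37) did not pass.

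In muscle at 7 days the AICAR and saline arrays did not overlap in 22 of the 25 called probes named. The deubiquitinase Usp15 (-0.93 ± 0.28, adjusted p = 0.0295) lost its call without 7-day replicate 2 or 3 or saline replicate 1 or 4 (-0.87 to -0.73, adjusted p = 0.0745 to 0.0989) and with no filter (adjusted p = 0.0524). The phosphatase Dusp2 (-0.91 ± 0.27, adjusted p = 0.0267) lost it without 7-day replicate 3 or 4 or saline replicate 3 or 4 (-0.89 to -0.74, adjusted p = 0.0589 to 0.0910), and Cpt1b without 7-day replicate 3 (0.32, adjusted p = 0.0512). Median scaling, which moved the median of all probes from -0.08 to -0.24, gave 4802 probes of which 21.5% were higher in place of 55%, and Cpt1b was then 0.18 and not past, while Prkaa2 (-0.57, adjusted p = 0.0152) and Ppargc1a (-0.43, adjusted p = 0.0217) passed. The authors' series values gave 4043 probes, 36.8% of them higher. Ppargc1a at -0.19 (adjusted p = 0.0118) and Slc2a4 at 0.13 (adjusted p = 0.0175), both in units of array SD and not log2, passed there. Prkaa2 also passed without background correction (adjusted p = 0.0459) and in a fit of the compared groups alone (adjusted p = 0.0434). Lists called rose from 0 to 11 in the authors' series values, 2 with no filter, 1 for probes detected on all 16 arrays, 2 with array weights, 2 without 7-day replicate 1, 3 without saline replicate 1 and 1 without saline replicate 2. Across 2331 genes the 7-day changes of the 2 brightest probes had r = 0.14. Where both passed, 94 of 134 pairs (70.1%) went the same way.

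After 14 days muscle differed from saline at 2441 probes, 1427 higher and 1014 lower. Gng5 rose 5.39-fold (2.43 ± 0.14, n = 4, adjusted p = 3.8e-09), Mxi1 4.51-fold (2.17 ± 0.10), Map2k1 4.32-fold (2.11 ± 0.13), Tma7 4.14-fold (2.05 ± 0.15) and the membrane-contact protein gene Vapa 4.08-fold (2.03 ± 0.10). The major urinary protein gene Mup2 was 4.25-fold higher (2.09 ± 0.61, adjusted p = 0.0238), with its other probe at 1.24 and past. Ktn1, 2 ± 0.16 at its brightest probe, was 0.54 and past at a second and -0.08 at the other. Cfl1, undetected at 14 days, was at least 1.83-fold lower, the RNA exonuclease Xrn1 -1.03 ± 0.12, the centrosome gene Cep63 -0.99 ± 0.15 and Tmem131l -0.92 ± 0.17. The chemokine receptor Ackr3 was at least 1.12-fold lower and the actin regulator Wasf2 at least 1.30-fold, both undetected at 14 days.

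Respiratory complexes II to V were the only called list in muscle at 14 days. Of all 9030 genes tested, 938 rose and 675 fell on their brightest probe. Of 38 genes of complexes II to V 9 rose and 0 fell (9 and 1 adjusted over the list alone, adjusted p = 0.019, 0.870 with an estimated correlation), with Atp5e at 1.73 ± 0.13, Atp5a1 at 1.72 ± 0.10, Sdhd at 1.65 ± 0.12 and Cox7b at 1.46 ± 0.08. The list's median was 0.01 and its mean 0.24, since 29 members did not pass, and under median scaling its median was -0.20, 0.05 above that of all probes, with no list called. Of 32 complex I genes 6 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.203), with Ndufb4 at 1.91 ± 0.11 and Ndufb2 at 1.54 ± 0.09. Of 15 TCA cycle genes 4 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.284), the E3 subunit Dld at 1.88 ± 0.15 and the oxoglutarate dehydrogenase subunit Ogdh at -0.41 ± 0.08, while Sucla2, undetected in saline, was at least 2.41-fold higher. The list call ended without 14-day replicate 3 or saline replicate 3 or 4, and the authors' series values gave 10 called lists.

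Other groups at 14 days held rises among members that mostly did not pass. Of 28 proteasome genes 6 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.196), with Psmd6 at 1.74 ± 0.12 and Psmc6 at 1.6 ± 0.19. Of 22 autophagy genes 5 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.269), with the autophagosome proteins Map1lc3b at 1.23 ± 0.09 and Gabarapl2 at 1.23 ± 0.19. Of 20 heat shock and unfolded protein genes 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.203), Hspa5 at least 2.87-fold higher. Of 23 matrix genes 2 rose, Col3a1 (1.34 ± 0.25) and Col1a2 (1.02 ± 0.24), and 3 fell (2 and 4 adjusted over the list alone, adjusted p = 0.203), among them the collagen cross-linking enzyme Lox (-0.58 ± 0.17, adjusted p = 0.0223). Of 12 macrophage and leukocyte markers 3 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.675), the MHC class II chain H2-Aa at 1.29 ± 0.23, the macrophage marker Adgre1 at 1.12 ± 0.21, and Ctss, undetected in saline, at least 1.58-fold higher. Of 21 fast fibre genes 3 rose, also adjusted over the list alone (adjusted p = 0.269), including the myosin heavy chains Myh1 (0.93 ± 0.20, second probe 2.37 and past) and Myh4 (0.42 ± 0.09). Of 16 clock genes 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.516), with Nr1d2 at 0.92 ± 0.16 and at 1.56 on its second probe.

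AMPK subunit Prkaa2 was -0.47 ± 0.13 (adjusted p = 0.0205) and Cpt1b 0.34 ± 0.11 (adjusted p = 0.0346) in muscle at 14 days, and their other probes (-0.36 and -0.04) did not pass. Ppargc1a (-0.11 ± 0.09), Slc2a4 (0.13 ± 0.07), Pdk4 (-0.18 ± 0.36) and Ucp3 (-0.16 ± 0.37) did not pass. The AICAR and saline arrays did not overlap in any of the 42 called probes named. Cpt1b lost its call without any 1 array except 14-day replicate 4 and saline replicate 2 (0.27 to 0.35, adjusted p = 0.0585 to 0.102) and under median scaling (0.12), which also ended that of Myh4 (0.19). Prkaa2 lost it without saline replicate 1 or 3 (-0.46 and -0.44, adjusted p = 0.0518 and 0.0548) and in a fit of the compared groups alone (adjusted p = 0.0598). Mup2 lost it without 14-day replicate 3 or 4 or saline replicate 1 or 2 (1.74 to 2, adjusted p = 0.0546 to 0.0725) and with a trended, robust variance (adjusted p = 0.0541). Lox lost it without 14-day replicate 2, 3 or 4 or saline replicate 4 (-0.56 to -0.52, adjusted p = 0.0507 to 0.0700), and Wasf2 without saline replicate 1 or 2 (-0.71 and -0.70, adjusted p = 0.0591 and 0.0550). Median scaling put the median of all probes at -0.25 and gave 5298 probes of which 19.4% were higher, in place of 58.5%, and the authors' series values gave 3784, 38.9% of them higher. Across 2331 genes the 14-day changes of the 2 brightest probes had r = 0.15, and where both passed 87 of 124 pairs (70.2%) went the same way. For the difference between the tissues, measured on the saline arrays alone over 1989 genes, r was 0.80 and 1182 of 1373 such pairs (86.1%) went the same way. That difference lies within 1 block of sample numbers and covers other genes, so its values are not a like-for-like standard. Of 185 muscle probes at least 2-fold higher whose gene had another tested probe, 56 had another that passed upward, 10 another that passed downward and 119 neither.

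**Figure D4:**
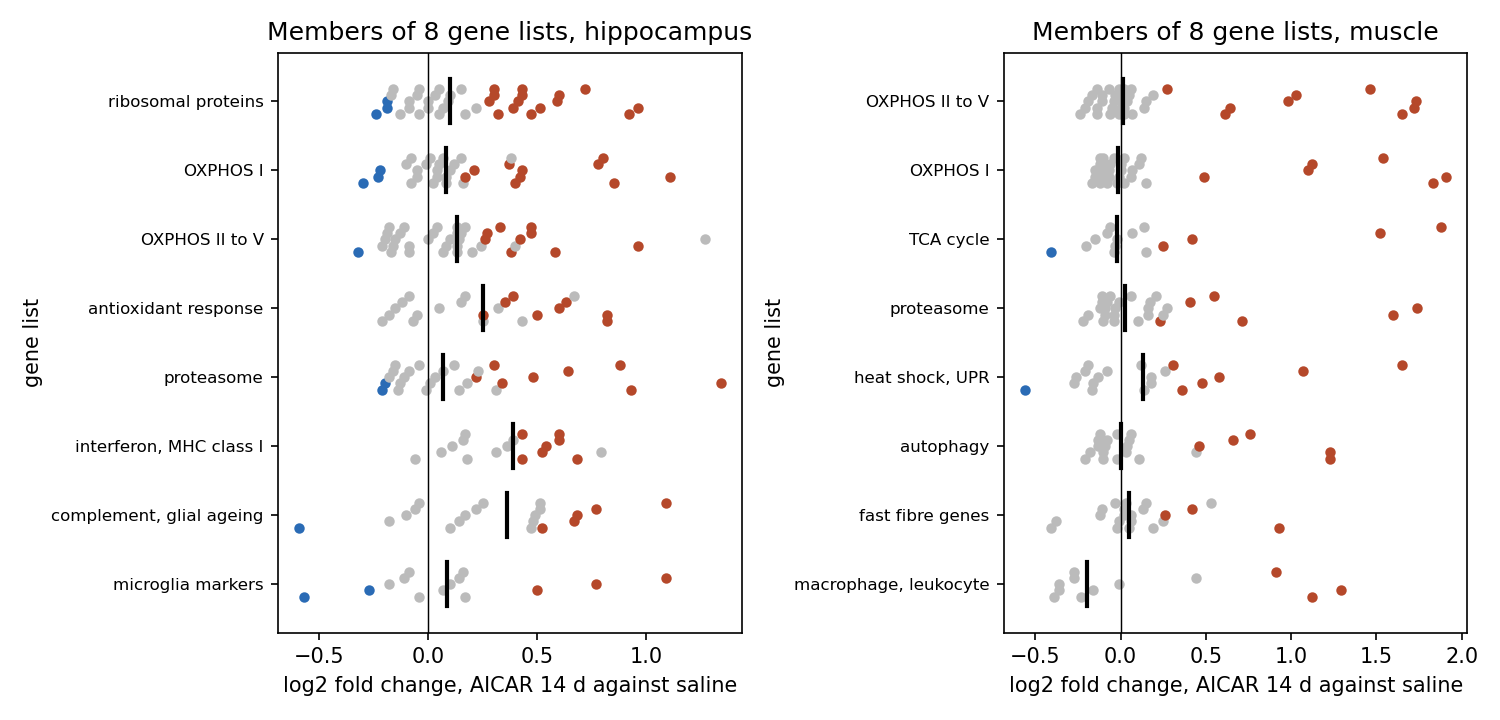
Log2 fold change of each measured member of 8 gene lists per tissue, 14 days against saline, with 1 point per gene, red for past and higher, blue for past and lower, grey for not past, and a bar at the list's median. In muscle a few members far above 0 lie beside most members near 0, as for complexes II to V with a median of 0.01 and 9 members past the threshold, and median scaling puts that median at -0.20.

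**Figure D5:**
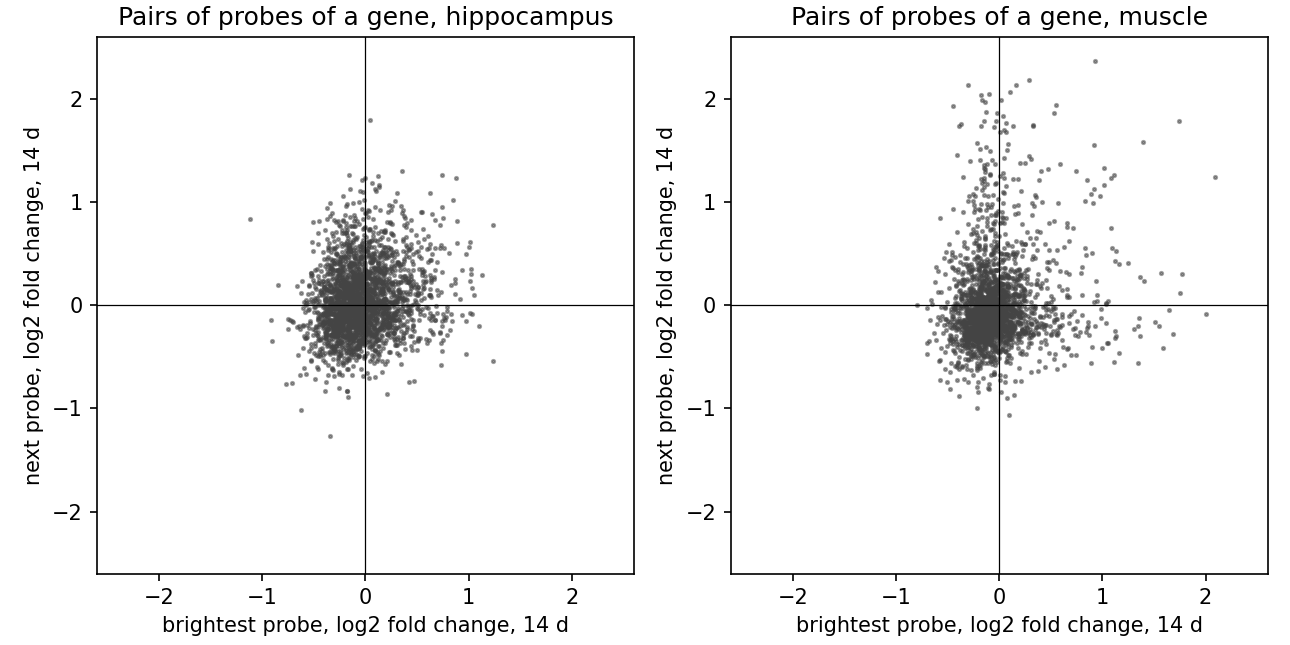
Change at 14 days against saline of the brightest probe (horizontal) and the next brightest probe (vertical) of each gene with several tested probes, log2 scale, 2432 genes in hippocampus and 2331 in muscle. In muscle many points lie along 1 axis, where 1 probe of a gene rose and the other stayed near 0 (r = 0.15).

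Between durations, muscle showed the same pairing of groups as hippocampus. Against 3 days, Gng5 was 2.22 ± 0.14 higher at 7 days and 2.34 ± 0.14 at 14 days (n = 4 per group), and Slc6a2 was -1.02 ± 0.18 at 7 days. At 14 days Mxi1 (2.16 ± 0.10), Ktn1 (2.06 ± 0.16), Dld (2.05 ± 0.15) and the ubiquitin ligase Huwe1 (2 ± 0.12) followed. The largest falls were Tmem131l (-0.94 ± 0.17), Xrn1 (-0.91 ± 0.12), Col1a1 (-0.89 ± 0.28, adjusted p = 0.0354) and Senp5 (-0.88 ± 0.24, adjusted p = 0.0172), with Mepce, undetected at 14 days, at least 1.33-fold lower. The other probes of Senp5 (-0.14 and 0.19) did not pass. In all, 2366 probes differed between 7 and 3 days (1365 higher, 1001 lower) and 2486 between 14 and 3 days (1427 higher, 1059 lower). By limma 0 differed between 14 and 7 days, 631 at an unadjusted p below 0.05, and 1 without 7-day replicate 1. Of the probes called against saline, 1251 rose and 578 fell at both durations, which share their saline arrays, and 0 moved in opposite directions. The 7- and 14-day changes had r = 0.92 across probes, and 0.79 with the saline arrays split so that none was shared. Simulations of unchanged groups that share the saline arrays gave a mean r of 0.48, with a range of -0.42 to 0.79. Col1a1 lost its call without 14-day replicate 2, 3 or 4 or 3-day replicate 1 or 2 (-0.88 to -0.72, adjusted p = 0.0681 to 0.111), with no filter (adjusted p = 0.0640) and with a trended, robust variance (0.0649), and Senp5 lost it without 3-day replicate 3 (-0.77, adjusted p = 0.0565).

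The change from saline differed between muscle and hippocampus at 1894 probes after 7 days and 1866 after 14 days. Huwe1 changed by 1.87 in muscle and -0.66 in hippocampus at 14 days, a difference of 2.54 ± 0.18 (adjusted p = 6.0e-11). Map2k1 (2.42 ± 0.28), Gm12657 (2.25 ± 0.27), the 14-3-3 protein gene Ywhae (2.24 ± 0.26) and Ptma (2.18 ± 0.19) also changed more upward in muscle. The ubiquitin ligase Rnf220 (-1.66 ± 0.20), Calml4 (-1.64 ± 0.49, adjusted p = 0.0215), Cnn3 (-1.62 ± 0.19) and Klhdc3 (-1.38 ± 0.14) changed more upward in hippocampus. At 7 days the largest differences were alpha-globin Hba-a1 (3.29 ± 1.13, adjusted p = 0.0444), Map2k1 (2.48 ± 0.28), Ptma (2.32 ± 0.19), Huwe1 (2.31 ± 0.18) and Ywhae (2.24 ± 0.26). In the other direction were Rnf220 (-1.77 ± 0.20), Fbxo46 (-1.59 ± 0.31) and Calml4 (-1.45 ± 0.49, adjusted p = 0.0411). By limma 0 of 11315 probes differed after 3 days, 970 at an unadjusted p below 0.05, where 566 would by chance, and 1 without hippocampal saline replicate 3.

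Muscle changed more upward at 792 of the probes at 7 days and 802 at 14 days, and less at 1102 and 1064. Under median scaling 5625 probes differed at 7 days and 3638 at 14 days, with 5.7% and 9.3% more upward in muscle in place of 41.8% and 43%. The authors' series values gave 3154 at 7 days, 30.4% of them more upward in muscle. Probes called in both tissues went the same way more often than independent calls would: at 14 days 339 rose in both where 168.4 would, and 289 fell in both where 162.1 would (Fisher's exact test across probes, which are not independent, p = 5.3e-43 and 2.7e-26). This overlap cannot tell a shared effect of AICAR from handling in blocks, because each block of sample numbers holds both tissues of 1 treatment. The same probes were compared, so a hybridization artefact of single probes could also be shared. The Hba-a1 difference lost its call without any of 12 of the 16 arrays (2.72 to 3.47, adjusted p = 0.0505 to 0.111). The other 4, without which it was kept, were hippocampal 7-day replicate 4, hippocampal saline replicate 1, muscle 7-day replicate 3 and muscle saline replicate 3. It was also lost with no filter (adjusted p = 0.0708) and with a trended, robust variance (0.0669). The Calml4 difference at 7 days was lost without any of 12 arrays, all but hippocampal 7-day replicate 4, hippocampal saline replicate 3, muscle 7-day replicate 4 and muscle saline replicate 1 (-1.49 to -1.21, adjusted p = 0.0513 to 0.103), with no filter (0.0649) and with a trended, robust variance (0.0542). At 14 days it was lost without hippocampal or muscle 14-day replicate 2 (-1.45 and -1.39, adjusted p = 0.0532 and 0.0558).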

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

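Tests chosen after the results were seen are the directions of same-gene probes, the stretches of sample numbers, and the residual blood test for each list alone. Of 244 gene values per group tested in hippocampus, 9 had 1 array far from the other 3, where chance gives about 12.2 (1 in 20). In muscle it was 10 of 212, where chance gives about 10.6. Arrays far above the others in hippocampus, on the log2 scale, were 14-day replicate 4 for Atxn2l (6.59), saline replicate 2 for Fech (6.35), 14-day replicate 2 for Gstm1 (11.15), 3-day replicate 3 for Numbl (7.37) and 14-day replicate 1 for Rps21 (13.56). Far below were 14-day replicate 3 for Prkaa2 (6.99), saline replicate 1 for Sox2 (7.95), 14-day replicate 1 for Uqcrb (10.34) and saline replicate 2 for the mean of both Ndrg1 probes (8.53). In muscle those above were 14-day replicate 4 for Ackr3 (4.83), 14-day replicate 2 for Atp5e (10.17) and for the mean of both Rab10 probes (9.30), 7-day replicate 1 for Rnf220 (5.70) and 3-day replicate 4 for Tmem131l (6.67). Saline replicate 3 stood above for Hbb-bt (7.50, the other 3 from 5.07 to 5.48). Those below were saline replicate 2 for Atxn2l (6.72), saline replicate 4 for Ctss (4.87) and Gng5 (7.70), and 14-day replicate 3 for Ktn1 (7.98). The background of hippocampal 7-day replicate 2 (152.3) lay far below that of the other 7-day arrays.

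The difference between muscle and hippocampus in the change from saline, tested as an interaction, stands out at 1894 probes at 7 days and 1866 at 14 days. At 7 days the named genes are Hba-a1 (3.29), Map2k1 (2.48), Ptma (2.32), Huwe1 (2.31), Ywhae (2.24), Rnf220 (-1.77), Fbxo46 (-1.59), Atxn2l (-1.56), C1qa (-1.47) and Calml4 (-1.45), as log2 change in muscle minus that in hippocampus. At 14 days they are Huwe1 (2.54), Map2k1 (2.42), Gm12657 (2.25), Ywhae (2.24), Ptma (2.18), Rnf220 (-1.66), Calml4 (-1.64), Cnn3 (-1.62), Klhdc3 (-1.38) and Atxn2l (-1.31). Atxn2l was undetected in hippocampal saline and C1qa in muscle at 7 days, so the size of their differences is not measured.

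Many probes changed at 7 and 14 days and none at 3 days. A hybridization artefact of single probes could give such calls and would leave 2 probes of a gene unrelated: their 14-day changes had r = 0.18 in hippocampus and 0.15 in muscle (at 3 days, within 1 set of arrays, 0.17 and 0.42), and where both passed, 63.7% and 70.2% of pairs went the same way, so the tests cannot tell. A difference in background between arrays would act most on dim probes. In hippocampus 37.8% of the brightest probes were called at 14 days against 17.2% of the dimmest. In muscle it was 17.6% against 15.9%, by a narrow margin (95% CI of the difference 0.14 to 3.33 points) and with 23% between them. These shares cannot tell, because dim probes lie near the background and may be called less often whatever the cause. Quantile normalization could also carry a background difference to brighter probes. Sets of arrays handled apart cannot be told from AICAR duration, since 0 stretches of 8 consecutive sample numbers hold more than 1 treatment. A lasting effect of 7 or more days of AICAR may also give this pattern, and the design cannot separate it from handling or, with saline given for 3 days only, from the number of injections.

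Calml4 and Ptgds were higher in hippocampus at 7 and 14 days. Choroid plexus tissue in the dissection could raise both. With the mean of the other 13 choroid plexus markers as a covariate, 85.7% of their mean 14-day change was kept. It was 77.8% for Calml4 and 94.9% for Ptgds, and the covariate itself was 0.8 higher than in saline. At 7 days the covariate was 0.05 higher, and 98.1% and 99.7% were kept. Choroid plexus as those markers measure it thus does not account for most of the change. A covariate that measures the tissue with noise removes too little, so choroid plexus is not excluded at 14 days. Calml4 at 14 days was 1.41 ± 0.23 with the covariate, in place of 1.81 ± 0.43, and Ptgds 1.47 ± 0.46, in place of 1.55 ± 0.44.

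The microglia and interferon lists were called higher in hippocampus at 3 days, calls that end with an estimated correlation (adjusted p = 0.494 and 0.565, n = 4), and 17 of 35 regroupings of the arrays give as many called lists. Residual blood could carry both, and with the 4 red blood cell markers as a covariate 78.5% of the mean change of the members was kept. For the interferon list alone it was 88.2%, and for the microglia list alone 63.2%. These shares cannot exclude blood, because the covariate rests on 4 red blood cell markers and does not measure other blood cells. With this covariate both lists had a camera adjusted p of 0.0489 at n = 4. An effect of AICAR itself on these lists was tested only by the comparison with saline.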

How the results depend on the processing

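No named gene that was called turned sign under any alternative. Of 264 named values 205 were called, and 165 kept their call under every alternative that tested their probe (142 of the 205 were tested among probes detected on all 16 arrays). Where a result below changed, the cause was not tested. With the authors' series values the called lists in hippocampus were 10 at 3 days, 0 at 7 and 2 at 14, and in muscle 7, 11 and 10. Called probes in muscle were then 39 at 3 days, 4043 at 7 and 3784 at 14, and the tissue difference at 7 days held 3154. With median scaling hippocampus had 2179 probes at 14 days, 1 for 14 against 7 days, and 0 lists at 7 and 2 at 14 days. Muscle had 4, 4802 and 5298 probes at 3, 7 and 14 days, 1 list at 3 days and 0 at 14, and the tissue difference was 5625 and 3638 at 7 and 14 days. Without background correction muscle had 13 probes at 3 days. With no filter there were 0 lists in hippocampus at 3 days and 2 in muscle at 7 days. For probes detected on all 16 arrays there were 2 lists in hippocampus at 3 days, 5 muscle probes at 3 days and 1 muscle list at 7 days. Array weights gave 2 lists in hippocampus at 3 days, 1 hippocampal probe for 14 against 7 days and 2 muscle lists at 7 days, and a trended, robust variance gave 10 muscle probes at 3 days. An unadjusted p with at least 1.5-fold change gave 27, 894 and 957 hippocampal probes at 3, 7 and 14 days, 870 and 893 for 7 and 14 against 3 days and 4 for 14 against 7. In muscle it gave 27, 1040, 1083, 995, 1025 and 19, and for the tissue difference at 3 days 115. An estimated correlation left 0 lists in hippocampus at 3, 7 and 14 days and 0 in muscle at 14. Alternatives added after the results were seen: genes whose detected probes all pass 1 way numbered 91 and 115 in hippocampus and 79 and 72 in muscle at 7 and 14 days, where 124, 144, 70 and 60 genes had probes past in both directions, and the mean over all probes of a gene gave 2 lists in muscle at 7 and at 14 days. With 1 array left out, called lists ranged from 0 to 6 in hippocampus at 3 days and 0 to 4 at 7 days, and in muscle from 0 to 1 at 3 days, 0 to 3 at 7 and 0 to 1 at 14. Called probes ranged from 0 to 1 in muscle at 3 days, in muscle for 14 against 7 days and for the tissue difference at 3 days. A replicate block gave 3391 and 3734 hippocampal probes and 2343 and 2300 muscle probes at 7 and 14 days, and 1736 and 1710 for the tissue difference, and 3 of the 205 named calls did not pass with it. These were Cpt1b in muscle at 14 days (adjusted p = 0.0599), Col1a1 in muscle at 14 against 3 days (0.0598) and the Hba-a1 difference between tissues at 7 days (0.0579). Arrays share only a number: same-numbered arrays had a mean r of -0.05 in hippocampus, with 4 of 24 pairs above 0.1, and -0.014 in muscle, with 2 of 24. The planned block by slide was not run, because the slide is not in the files used here. Signal over background limits dim probes: array backgrounds ran from 114.3 to 168.3, and the size of a change against an undetected group is not measured.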

Other observations

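The genes of this part were chosen after their values were seen: genes with several tested probes that all passed in the same direction at 14 days. Such genes numbered 115 in hippocampus and 72 in muscle, while 144 and 60 had probes past in both directions. The agreement of their probes is how these genes were chosen, so it is no separate support for them. In hippocampus the stress-response and myelin gene Ndrg1 rose by a mean of 1 over 2 probes (0.74 and 1.27, n = 4, largest adjusted p = 6.5e-05) and the chloride channel gene Ttyh2 by 0.75 (0.67 and 0.82). The neuronal transcription factor Mef2c fell by 0.82 (-1.01 and -0.62, largest adjusted p = 0.0073), Col6a1 by 0.76, the hyaluronidase Cemip2 by 0.62 and R3hdm1 by 0.60. Under median scaling Mef2c (-0.71, adjusted p = 0.0555), Col6a1 (-0.59), Cemip2 (-0.44) and R3hdm1 (-0.44) did not pass, and with no filter, which adds dim probes of the same gene, neither did Ttyh2 (0.53), Col6a1 (-0.56) or Cemip2 (-0.32).

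In muscle at 14 days the proteasome subunit Psmd6 rose by a mean of 1.76 over 2 probes (1.74 and 1.78, n = 4, largest adjusted p = 1.8e-07), the NAD-synthesis enzyme Nampt by 1.49 (1.39 and 1.59, 9.9e-06), Mup2 by 1.67 (1.24 and 2.09, 0.0278) and the vesicle GTPase Rab10 by 1.16 (1.08 and 1.23). The Hippo pathway gene Wwtr1 fell by 0.65, Klhl9 by 0.57 and Rasl11b by 0.63 (largest adjusted p = 0.0330). Klhl9 lost its call without 14-day replicate 2 or saline replicate 1 (-0.43 and -0.52, adjusted p = 0.0644 and 0.0549). Mup2 lost it without 14-day replicate 3 or 4 or saline replicate 1, 2 or 3 (1.42 to 1.70, adjusted p = 0.0538 to 0.0926), with no filter (0.0516) and with a trended, robust variance (0.0541). Rasl11b lost it without 14-day replicate 2 or 4 or saline replicate 3 or 4 (-0.62 to -0.45, adjusted p = 0.0650 to 0.116), with no filter (0.0540) and in a fit of the compared groups alone (0.09998).

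Regrouping the 8 arrays of a comparison in all 35 ways tests whether a count can arise by chance, with the real value and the highest of the others as follows. For hippocampus the real count was the highest at 7 days (3696, 1), 14 days (4033, 0), 7 against 3 days (3572, 2) and 14 against 3 days (3685, 1), each with 1 of 35 as large. That is the smallest share this test can give, and it was not corrected for the number of comparisons. For muscle the real count was the highest at 7 days (2558, 3), 14 days (2441, 23), 7 against 3 days (2366, 2) and 14 against 3 days (2486, 0), also with 1 of 35. Where the real count is 0, every regrouping is as large (35 of 35) and the test can exclude nothing: for hippocampus at 3 days (0, 5) and 14 against 7 days (0, 0), for muscle at 3 days (0, 1) and 14 against 7 days (0, 1), and for the lists of muscle at 3 days (0, 7) and 7 days (0, 10). Chance cannot be excluded for the lists of hippocampus at 3 days (4, 10, with 17 as large), 7 days (2, 11, with 21) and 14 days (6, 11, with 9), or of muscle at 14 days (1, 6, with 20). A real count that no other regrouping reaches does not exclude handling in blocks, which would also set the real groups apart.

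For the tissue difference, 100 regroupings were used. They break the groups of both tissues, so they ask whether anything changed in either tissue and not whether the tissues differ. The real count and the highest other were 1894 and 2407 at 7 days and 1866 and 1950 at 14 days, each with 2 of 100 as large, and 0 and 7 at 3 days, with 100 of 100. The regroupings with counts above 100 probes, 5 at 7 days and 3 at 14 days, all kept the real groups of 1 tissue or their mirror image, and among those that kept neither the highest was 2 at 7 days and 47 at 14 days.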
